A study of Danio rerio with 6 samples.

How the data were processed

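Whole zebrafish embryos at 5 days post fertilization were compared, 3 libraries of wild type and 3 of sas10 mutants. The labels describe polyA RNA. Per the submitters' processing notes, the tools named were fastp 0.20.0, HISAT2 2.2.1, featureCounts 2.0.1, Salmon 0.12 and DESeq2 1.40.2, with the genome build GRCz11. The deposited gene table holds raw counts of reads per gene; per the file headers, the authors made it with featureCounts 2.0.1, counting exons summed by gene for read pairs, on the Ensembl GRCz11 annotation of release 105, with no strand option in the command. Reads of overlapping or antisense genes are therefore uncertain, as are those of near-identical copies. The second deposited table gives the authors' own comparison of the genotypes, with log2 fold changes and their standard errors, p-values and adjusted p-values; it holds no values per library. The third deposited table gives, for regions of the 45S ribosomal RNA precursor, whole numbers of reads and then TPM values that sum to 1000000 per library. Per the labels, the authors scaled those reads as TPM with the precursor taken as the whole genome. Salmon is named in the processing notes, and the table itself names no tool.

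The columns of the gene count table show the genotype of each library, with s1, s2 and s3 taken as sas10 mutants and wt11, wt12 and wt13 as wild type, but not which numbered replicate it is, so they are named by their headings. The precursor table numbers its libraries 1 to 3 in each genotype. Replicate pairs of count columns differed by more than sampling noise (chi-square per degree of freedom 7.71 to 32.7), so none was taken as a repeated deposit of another; that the libraries are biological repeats is per the labels. Gene symbols came from a name table that matched 29201 of 32520 gene identifiers, and they are written in lower case. That table gives some duplicated genes 1 shared symbol.

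Gene counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, default filtering by expression (21708 genes kept, 10812 left out), robust dispersion estimates and the quasi-likelihood test of mutant against wild type. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the quasi-likelihood statistic. The coefficient of biological variation was 0.146. The p-values measure the spread between these samples. Values per library are given as CPM on scaled library sizes. The script was tested on simulated counts for 21708 genes of this comparison: it recovered 29.9% of changes of 1.5-fold, 64.2% of 2-fold and 93.9% of 4-fold, with 14 false among 139 calls. That simulation changed 67, 67 and 66 genes at these sizes, far fewer than the 13508 called in the data. An adjusted p is harder to pass when few genes change, so these shares need not hold for the data.

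Before the data were examined, 22 gene lists were fixed: SSU processome, large subunit assembly, RNA polymerase I and nucleolus, RNA exosome and nuclear RNA decay, small and large subunit ribosomal proteins, integrated stress response, unfolded protein response, hepatocyte, exocrine pancreas, endocrine pancreas, intestine, skeletal muscle, photoreceptor and lens, neuron and glia, cartilage, erythroid, myeloid and lymphoid, inflammation and acute phase, proliferation, and autophagy and lysosome, with 1 more that is left out of the text. Of 656 listed symbols, 39 were not matched. For 69 symbols the copies under a shared name were taken, a rule set after the name table was seen and before any model was fitted. Lists were tested with camera from limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 22 lists, again with a correlation estimated per list, and with fry. No camera call of these lists held with the estimated correlation.

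Genes named in the text were set by a rule fixed in advance: utp3, mdm2 and cdkn1a among others fixed by name; the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM, a real symbol and no overlap between genotypes; and the 2 called members of each list with the largest change in its majority direction. Some genes the rule takes are left out of the text. Other names are stated to have been chosen after their values were seen. A group at 0 counts was given a floor of 3 counts over the group, and ratios with 1 to 6 counts in a group carry exact 95% intervals. Intervals and floors cover counting error only. Precursor regions were compared with exact two-sided permutation tests of mean log2(TPM + 1), adjusted over 6 regions. The pseudocount of 1 understates changes of low regions.

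Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no filter beyond 1 count, a stricter filter (at least 1 CPM in 3 libraries and 100 counts), DESeq2 1.42.0, limma voom, a threshold on fold size, each library left out in turn, a replicate block, other pseudocounts, limma on TPM and scaling to 28S. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9 was used for joining, exact tests and figures. Genome sequence was not used here.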

Results

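Sas10, encoded by utp3 in zebrafish, is a nucleolar protein of the small subunit (SSU) processome, the particle that processes the precursor of 18S ribosomal RNA. RNA sequencing was done on whole zebrafish embryos at 5 days post fertilization, with 3 libraries of sas10 mutants and 3 of wild type. Total gene counts ran from 17599625 to 19718753 per library, and mitochondrial genes took 5.97% to 7.37% of them. The first principal component of log2 CPM (counts per 1000000 counts) held 85.8% of the variance and separated the genotypes. Correlations of log2 CPM across genes were at least 0.973 within a genotype and at most 0.875 between genotypes. The wild type library headed wt11 stood furthest from its own group, with a second component score of 42.3, against scores from -27.4 to 9.3 in the other libraries. The labels call the libraries biological repeats and do not say from which clutches they came.

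The first comparison asked whether the targeted transcript itself differed, which checks the labels. The utp3 gene (ENSDARG00000056720, GRCz11 chromosome 11, 26370381 to 26375575) was at 32.3 ± 4.43 CPM in wild type and 10.8 ± 0.42 CPM in sas10 mutants (SD, n = 3 each). Its log2 fold change was -1.58 ± 0.13 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.53e-06), and all 3 mutant libraries lay below all 3 wild type libraries. The genes mdm2 and cdkn1a, fixed in advance, were read in the same way. The ubiquitin ligase gene mdm2 rose from 40.2 ± 4.95 to 263 ± 12.6 CPM (log2 2.71 ± 0.13, adjusted p = 1.18e-08). The cell cycle inhibitor cdkn1a rose from 10.8 ± 4.34 to 100.7 ± 5.02 CPM (log2 3.21 ± 0.23, adjusted p = 1.77e-06).

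**Figure D1:**
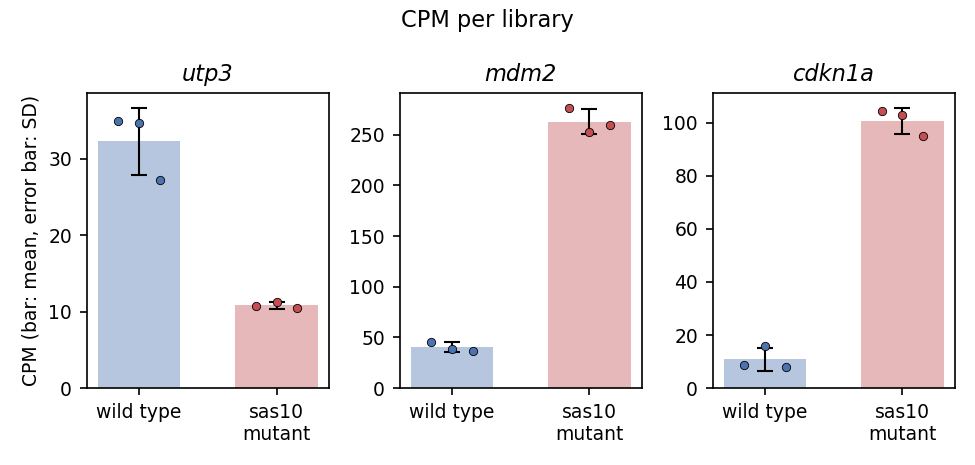
CPM of utp3, mdm2 and cdkn1a in each of the 3 wild type and 3 sas10 mutant libraries (points), with the mean (bar, axis from 0) and SD (error bar). The mutant points for utp3 sit at 10.5 to 11.3 CPM, below all of its wild type points, and those of the other genes sit above their wild type points.

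How widely did gene expression differ between the genotypes? The transcriptome differed broadly: 6614 genes were higher and 6894 lower in the mutants among 21708 tested (edgeR, adjusted p under 0.05). Called genes were thus 62.2% of those tested, the share against which counts within the gene lists and families below are to be read. Changes of at least 2-fold made up 2865 of the increases and 3564 of the decreases. At 4-fold, 625 genes were higher and 1055 lower. The 3 mutant libraries lay entirely above or below the 3 wild type libraries for 67.6% of tested genes, against 10% by chance. Without wt11, 7129 genes were higher and 7138 lower.

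Which genes differed most? The largest increases were in secreted signals, an acute phase protein and a scpp family gene. The leptin gene lepb had 2 counts over all wild type libraries and a mean of 172.6 ± 13.6 CPM in the mutants, a ratio of 4879 with a counting interval of 1350 to 40290. The interleukin 11 gene il11a rose from 0.10 ± 0.10 to 39.7 ± 14.0 CPM (log2 8.46 ± 0.46, adjusted p = 3.03e-07). It had 6 counts over the wild type libraries, a ratio of 372.4 with an interval of 170.8 to 1016. For il11b, which had 2 wild type counts, the mutant mean was 11.4 ± 3.79 CPM and the ratio 322, with an interval of 88.7 to 2663. The inflammatory cytokine il1b rose from 0.85 ± 0.18 to 165.1 ± 113.1 CPM (log2 7.59 ± 0.78, adjusted p = 0.000458), and scpp8 rose from 0.90 ± 0.27 to 171.2 ± 76.7 CPM (log2 7.56 ± 0.51, adjusted p = 1.11e-05). Acute phase gene saa2 reached 23.0 ± 22.2 CPM in the mutants from 0.07 ± 0.03 in wild type (log2 8.21 ± 1.44, edgeR adjusted p = 0.00475). It had 4 counts over the wild type libraries, a ratio of 322.3 with an interval of 125.6 to 1185. Single libraries moved some of these values: the log2 fold change was 7.07 for saa2 and 6.91 for il1b without mutant library s2 and 9.37 for il11a without wild type library wt13. The fitted value of il11b, which rests on its wild type counts, also moved by over 1.5 times without wt13, the library that holds both counts. With limma voom the saa2 difference did not pass (log2 7.46, adjusted p = 0.0716).

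The largest decreases were in genes of the digestive organs and a keratin. One copy of the zymogen granule gene sycn (ENSDARG00000103687) fell from 241 ± 53.8 CPM to 1 count over the mutant libraries, a ratio of 13460 with a counting interval of 2416 to 531800. Without mutant library s2, which holds that count, the mutants had 0 counts of it. No count of a mep1b copy (ENSDARG00000037533), for a brush border metalloprotease subunit, was seen in the mutants (31.2 ± 8.89 CPM in wild type), which makes it at least 587-fold lower against a floor of 3 counts over the group. The keratin gene krt93 also had 0 mutant counts (10.5 ± 1.65 CPM in wild type) and was at least 197-fold lower by the same floor. Transcripts of pancreatic enzymes fell as well. The elastase gene ela2 went from 2592 ± 644.1 to 1.16 ± 0.80 CPM (log2 -11.12 ± 0.43, adjusted p = 1.98e-08; -11.79 without mutant library s1), the trypsin-like prss59.1 from 3015 ± 735.5 to 1.43 ± 0.46 CPM (log2 -11.04 ± 0.32, adjusted p = 6.04e-10), and the amylase amy2a from 1254 ± 299.7 to 0.66 ± 0.33 CPM (log2 -10.88 ± 0.34, adjusted p = 1.09e-09).

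The next comparison asked what genes of ribosome assembly did in embryos mutant for an assembly factor. All of the 52 tested SSU processome genes were called: 51 rose, and utp3 fell (median log2 1.2, camera adjusted p = 1.33e-14). With an estimated correlation the adjusted p = 0.302. The assembly factor gene imp4 rose from 12.1 ± 1.82 to 46.2 ± 2.59 CPM (log2 1.93 ± 0.13), and a copy of snu13 (ENSDARG00000023299), for a box C/D snoRNP protein, from 30.7 ± 5.58 to 107.0 ± 6.34 CPM (log2 1.80 ± 0.14). Of 43 large subunit assembly genes, 39 rose and 3 fell (median log2 1.13, camera adjusted p = 8.19e-10, and adjusted p = 0.308 with an estimated correlation). Examples were rpf1 (log2 1.77 ± 0.11) and ppan (log2 1.70 ± 0.11). The genes that fell, gtpbp4 (log2 -1.01), nsa2 (log2 -0.94) and nop53 (log2 -0.63), were named after their values were seen. Among 22 genes of RNA polymerase I and the nucleolus, 17 rose and 2 fell (median log2 0.98, camera adjusted p = 0.000158, and adjusted p = 0.308 with an estimated correlation). The polymerase subunit genes polr1h (log2 1.84 ± 0.26) and polr1d (log2 1.80 ± 0.17) were among those that rose, while ubtfl (log2 -0.69) and npm1b (log2 -0.50), picked after the fact, fell; 1 gene of this list fell without s2, s3, wt12 or wt13. Of 23 genes of the RNA exosome, which degrades and trims nuclear RNA, and of nuclear RNA decay, 18 rose and 2 fell (median log2 0.78, camera adjusted p = 0.000158, and adjusted p = 0.28 with an estimated correlation). The exosome subunit genes exosc9 (log2 2.02 ± 0.13) and exosc2 (log2 1.89 ± 0.19) rose; exosc1 (log2 -1.51) and the poly(A) polymerase gene tent4b (log2 -0.69), named after their values were seen, fell. Adjusted over the list alone, the counts in these 4 lists were the same.

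Genes for the ribosomal proteins themselves were mostly not called. Among 34 small subunit genes, 2 fell and 32 were not called (median log2 -0.02, camera adjusted p = 0.913), and the counts adjusted over the list alone were the same. Among those that fell was rps9, from 1202 ± 253.4 to 556.6 ± 52.4 CPM (log2 -1.11 ± 0.17). Of 45 large subunit genes, 9 fell, 1 rose and 35 were not called (median log2 -0.14, camera adjusted p = 0.36); adjusted over the list alone, 0 fell and 0 rose by edgeR. The examples were rpl13 (log2 -0.62 ± 0.18, adjusted p = 0.0116) and rpl10a (log2 -0.57 ± 0.16, adjusted p = 0.00925). The gene that rose was an rpl5 copy (ENSDARG00000020197, log2 0.52), named after its value was seen; the other rpl5 copy (ENSDARG00000015862, log2 -0.43) fell. These counts rested on single libraries. Without wt11, 10 small subunit and 8 large subunit genes rose, with 2 and 5 falling, and the medians turned to 0.21 and 0.10, and without wt13, 5 small subunit and 17 large subunit genes fell and the large subunit list passed (camera adjusted p = 0.00508). Without mutant library s3, 2 large subunit genes fell and rpl13 did not pass (log2 -0.55, adjusted p = 0.0579); without s1, s2 or wt12, the large subunit genes that fell numbered 5, 4 and 5.

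Did stress response genes differ? Of 24 integrated stress response genes, 16 rose and 5 fell (median log2 1.1, camera adjusted p = 0.000692, and adjusted p = 0.302 with an estimated correlation). The transcription factor genes cebpb, from 22.5 ± 4.39 to 618.2 ± 55.5 CPM (log2 4.78 ± 0.18), and atf3, from 10.4 ± 2.72 to 153.0 ± 17.0 CPM (log2 3.88 ± 0.18), rose most. The members that fell were nupr1b, slc7a11, slc3a2a, gpt2 and shmt2, at log2 fold changes of -2.0, -0.73, -0.46, -0.43 and -0.39, again named after the fact. Of 20 genes of the unfolded protein response, which adjusts chaperones of the endoplasmic reticulum, 14 rose and calr (log2 -0.39, named after its value was seen) fell (median log2 0.63, camera adjusted p = 0.000927, and adjusted p = 0.28 with an estimated correlation). The chaperone gene hyou1 (log2 1.90 ± 0.12) and the secreted factor gene manf (log2 1.61 ± 0.12) rose; 2 genes of this list fell with upper-quartile scaling or without wt13. In the list of inflammation and acute phase genes, 24 of 26 rose and 0 fell by edgeR at an adjusted p under 0.05 (median log2 3.84, camera adjusted p = 8.35e-12, and adjusted p = 0.28 with an estimated correlation). The members that were not called, egr1 and hamp, had log2 fold changes of 1.19 and 1.44. Counts adjusted over the list alone were the same in these 3 lists.

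Digestive organ markers were then compared. Of 28 exocrine pancreas genes, 26 fell and 2 rose (median log2 -7.48, camera adjusted p = 6.57e-15, and adjusted p = 0.28 with an estimated correlation). One gene that rose was amy2al1 (0.94 to 2.57 CPM), named after its value was seen. Of 35 intestine genes, 30 fell and 2 rose (median log2 -3.27, also with the gene at 0 counts set to its bound; camera adjusted p = 1.43e-12, and adjusted p = 0.28 with an estimated correlation). The chitinase gene chia.2 fell from 2156 ± 280.9 to 4.23 ± 0.94 CPM (log2 -8.99 ± 0.23, adjusted p = 3.99e-10). This gene lies on chromosome 11 (24001993 to 24008739), within 10 Mb of utp3. An effect of alleles linked to utp3 on it was not tested. The members that rose were agr2 (log2 1.66) and apoa4a (log2 0.81), named after the fact. Among 33 hepatocyte genes, 21 fell and 8 rose (median log2 -1.08, camera adjusted p = 0.00089, and adjusted p = 0.473 with an estimated correlation). The thyroid hormone carrier gene ttr fell from 58.5 ± 13.8 to 0.57 ± 0.10 CPM (log2 -6.66 ± 0.24), and the plasma glycoprotein gene ahsg1 fell from 22.9 ± 2.53 CPM to 3 counts over the mutant libraries, a ratio of 428.9 with an interval of 146.4 to 2082. Mutant library s1 held most of these counts, and the fitted value of ahsg1 moved by over 1.5 times without it. Adjusted over the list alone, 22 hepatocyte genes fell and 8 rose, and counts of the pancreas and intestine lists were the same. Among 16 endocrine pancreas genes, 9 fell and 4 rose (median log2 -0.75, camera adjusted p = 0.386); adjusted over the list alone, 9 fell and 5 rose. The fall of pdx1, a pancreatic transcription factor gene, was log2 -2.01 ± 0.34, and that of the prohormone convertase gene pcsk1 was -1.60 ± 0.28. The hormone genes ins (log2 1.05), sst1.2 (log2 1.17), gcg (log2 2.08) and gcga (log2 3.29) rose and were named after their values were seen.

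**Figure D2:**
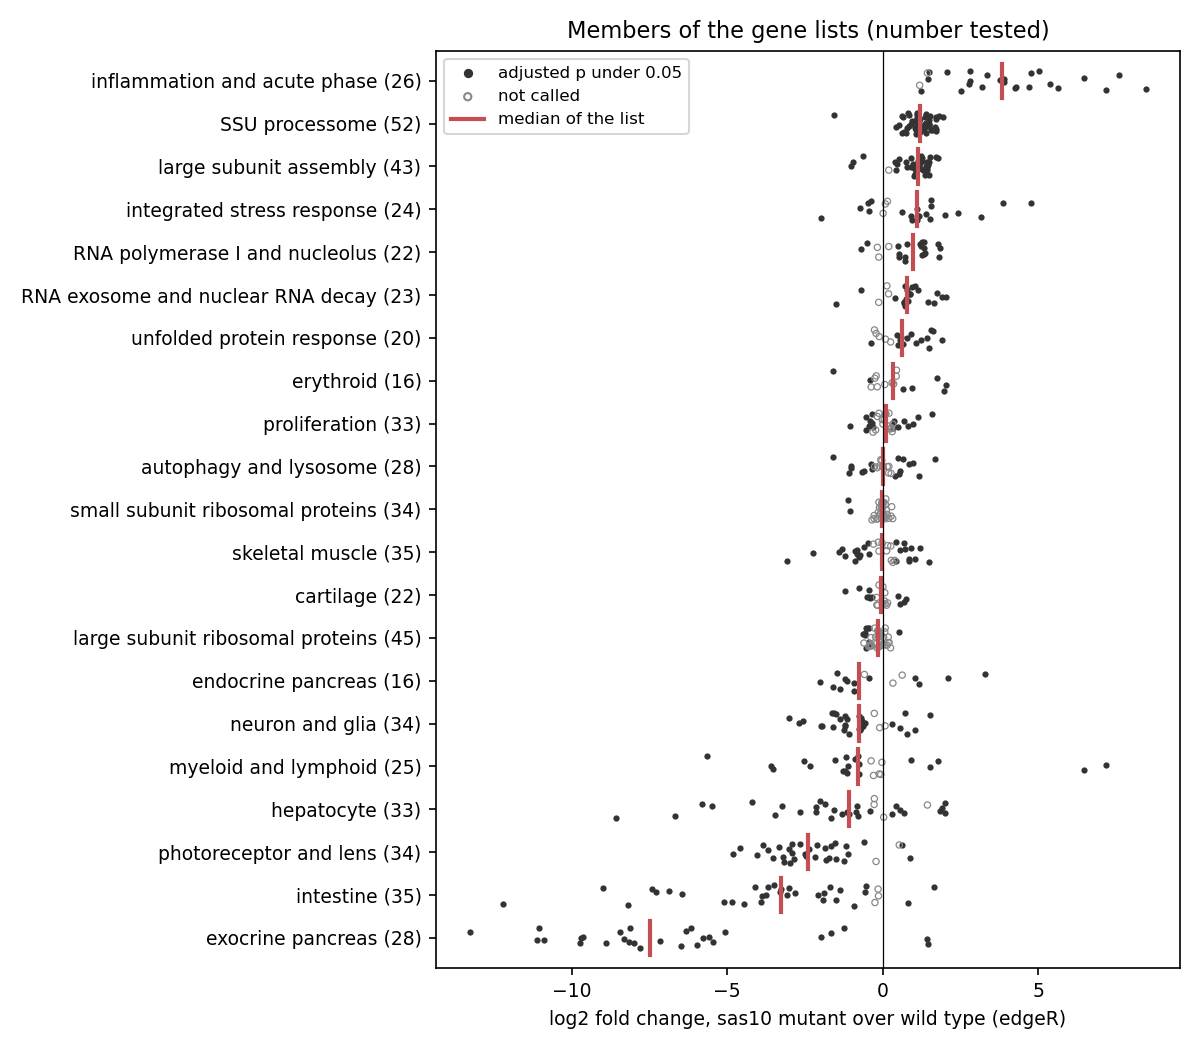
Log2 fold change (edgeR, sas10 mutant over wild type, horizontal axis) of each tested member of the gene lists described here, with filled points for adjusted p under 0.05, open points for genes not called and a red line at the list median. Medians run from -7.48 for the exocrine pancreas to 3.84 for inflammation and acute phase genes.

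Markers of other tissues were compared next. Of 34 photoreceptor and lens genes, 30 fell and 2 rose (median log2 -2.41, camera adjusted p = 1.77e-09, and adjusted p = 0.28 with an estimated correlation). The cone phosphodiesterase subunit gene pde6ha fell from 545.3 ± 79.3 to 22.6 ± 5.59 CPM (log2 -4.59 ± 0.21). The lens crystallin gene crybb1 fell from 387.4 ± 270.1 to 14.0 ± 7.13 CPM (log2 -4.80 ± 0.78, adjusted p = 0.00399; -4.09 without wild type library wt12). The genes that rose were nr2e3 (log2 0.61) and a rho copy (ENSDARG00000103574, log2 0.89), named after the fact; neither passed without mutant library s2, and 1 gene of the list rose without wt11. Among 34 neuron and glia genes, 25 fell and 6 rose (median log2 -0.76, camera adjusted p = 0.00089, and adjusted p = 0.399 with an estimated correlation); adjusted over the list alone, 26 fell and 6 rose. A copy of the glutamate transporter gene slc1a2 (ENSDARG00000052138, log2 -3.03 ± 0.37) and the myelin protein gene mpz (log2 -2.69 ± 0.14) fell. Of 25 myeloid and lymphoid genes, 15 fell and 5 rose (median log2 -0.78, camera adjusted p = 0.0156, and adjusted p = 0.357 with an estimated correlation). The recombinase gene rag1 of developing lymphocytes fell from 11.8 ± 1.84 to 0.97 ± 0.43 CPM (log2 -3.59 ± 0.27). A ccr9 copy (ENSDARG00000099738) fell to 2 counts over the mutant libraries, a ratio of 59.7 with an interval of 16.2 to 498.3, both in library s1, without which the mutants had 0 counts. The genes that rose were the metalloprotease genes mmp9 (log2 7.17) and mmp13a (log2 6.46), both also in the inflammation list, and a copy each of mpeg1 (ENSDARG00000043093, log2 1.77) and cxcr4 (ENSDARG00000057633, log2 1.52), and marco (log2 0.91), named after their values were seen.

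Several lists did not pass as sets. Of 35 skeletal muscle genes, 14 fell and 11 rose (median log2 -0.02, camera adjusted p = 0.801); the members that fell furthest were copies of tnni2, for a fast troponin subunit (ENSDARG00000045592, log2 -3.08 ± 0.19; ENSDARG00000035958, log2 -2.25 ± 0.15), while another tnni2 copy (ENSDARG00000029069, log2 1.47), named after its value was seen, rose. The median of the list turned to 0.12 without wt11. Of 22 cartilage genes, 7 fell and 4 rose (median log2 -0.07, camera adjusted p = 0.706), with acanb (log2 -1.22 ± 0.15) and epyc (log2 -0.77 ± 0.10) among those that fell; without mutant library s3, 4 fell. The genes that rose, named after their values were seen, were a sox9 copy (ENSDARG00000043923, log2 0.75), matn1 (log2 0.67), hapln1a (log2 0.57) and col11a1b (log2 0.48). Of 16 erythroid genes, 5 rose and 2 fell (median log2 0.33, camera adjusted p = 0.362). The embryonic globin gene hbae3 rose from 96.1 ± 23.0 to 393.2 ± 116.4 CPM (log2 2.03 ± 0.23) and the heme synthesis gene hmbs (ENSDARG00000008840) by log2 1.97 ± 0.16, while rhag (log2 -1.59) and an slc4a1 copy (ENSDARG00000024560, log2 -0.42) fell and were named after the fact; 1 erythroid gene fell without s2, s3, wt11 or wt12 and by DESeq2, and 3 without s1 or with upper-quartile scaling. Of 33 proliferation genes, 9 rose and 8 fell (median log2 0.10, camera adjusted p = 0.615); adjusted over the list alone, 7 rose and 8 fell. The survivin gene birc5 (log2 1.60 ± 0.20) and the replication licensing gene cdt1 (log2 1.13 ± 0.17) rose. Here 5 rose with upper-quartile scaling or without wt12, and 5, 4, 5 and 5 fell without s1, s2, s3 and wt12. The scaling also turned the median of the list to -0.03. Of 28 autophagy and lysosome genes, 9 rose and 8 fell (median log2 0.00, camera adjusted p = 0.789); the cathepsin genes ctsla (log2 1.68 ± 0.15) and ctsd (log2 1.18 ± 0.16) rose. In the skeletal muscle, cartilage, erythroid, autophagy and lysosome, photoreceptor and lens, and myeloid and lymphoid lists, counts adjusted over the list alone were the same as those over all genes.

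A further comparison asked how reads were spread over the regions of the ribosomal RNA precursor, from its external transcribed spacer (5'ETS) and internal spacers (ITS1, ITS2) to the mature rRNA regions, of which 18S and 28S are the largest. The spacer regions had higher mean shares in the mutants and 18S a lower one. The 5'ETS was at 11001 ± 6491 TPM (reads scaled for region length to sum to 1000000 within the precursor) in wild type and 143663 ± 74134 in mutants (SD, n = 3 each), a ratio of 13.1 and a log2 difference of 3.70. For ITS2 the means were 17871 ± 15419 and 80247 ± 22857 TPM, a ratio of 4.49; the log2 difference of 2.66 was 1.73 without wild type replicate 1 and 3.39 without wild type replicate 3. For 18S they were 422236 ± 104549 and 184330 ± 58415 TPM, 2.29 times higher in wild type. In TPM, every mutant library lay on the same side of every wild type library in each of these 3 regions. The exact two-sided permutation test on log2(TPM + 1) gave p = 0.1, the smallest that 3 against 3 can reach (adjusted p = 0.2 over 6 regions). Scaled to 28S, the 5'ETS and ITS2 differences were 3.785 and 2.745 (exact permutation p = 0.1 each). That of 18S was -1.14 (exact permutation p = 0.2). As a share of precursor reads, 18S overlapped, at 18.89% in mutant replicate 3 and 18.81% in wild type replicate 2. ITS1 was at 8267 ± 9017 and 51462 ± 30116 TPM with overlapping groups (exact permutation p = 0.2, adjusted p = 0.3); the log2 difference of 2.95 was 3.82 without wild type replicate 3 and 3.62 without mutant replicate 1. The 28S values, 540625 ± 88709 and 525153 ± 185606 TPM, differed by less than the spread between replicates (exact permutation p = 0.9). The short mature region between ITS1 and ITS2 had 0 reads in every wild type library and 6, 0 and 3 reads in the mutants, so no fold is given.

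The read numbers behind these shares were small for the spacers. The 5'ETS held 455, 62 and 50 reads in wild type replicates 1, 2 and 3 and 1015, 820 and 951 in the mutants. ITS1 held 3 to 35 reads in wild type and 39 to 47 in mutants, and ITS2 21 to 68 and 99 to 208. Total precursor reads spanned 27.3-fold among wild type libraries (23911 to 653430) and 5.57-fold among mutants (29376 to 163517). TPM values of a library sum to a fixed total, so the regions are not independent. The labels describe polyA RNA, so these reads are those that passed that selection and need not follow levels of rRNA. With limma, the 5'ETS difference passed (adjusted p = 0.0176).

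**Figure D3:**
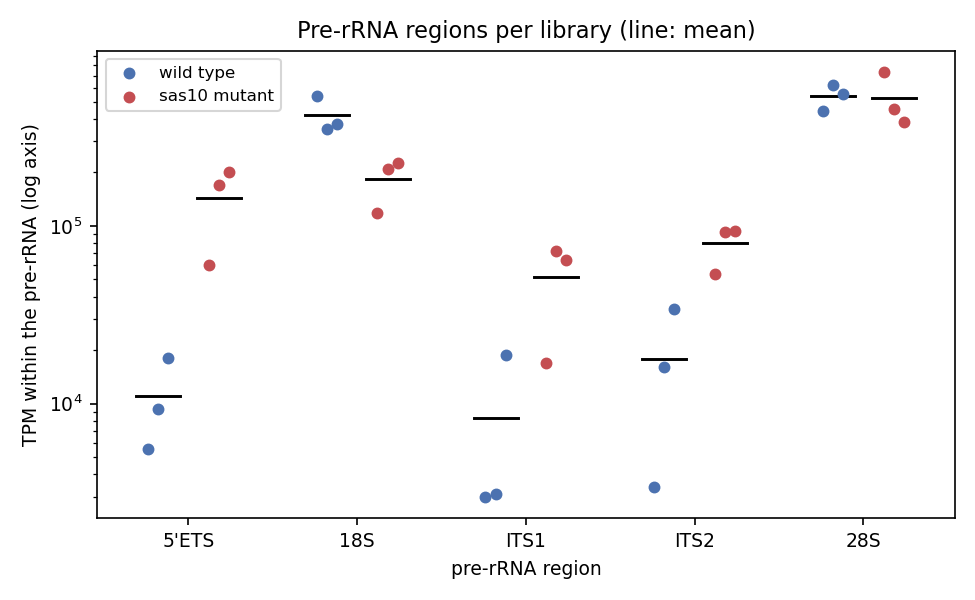
TPM within the ribosomal RNA precursor (vertical log axis) for 5 regions in each of 3 wild type and 3 sas10 mutant libraries (points), with a line at the group mean. Mutant points lie above all wild type points for the 5'ETS and ITS2 and below them for 18S; the short mature region between ITS1 and ITS2 is left out because wild type libraries had 0 reads there.

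The last comparison asked how far this fit and the authors' deposited table of differential expression gave the same genes. The authors' deposited table listed 8574 genes, 4117 with positive and 4457 with negative log2 fold changes, with a smallest absolute log2 fold change of 0.59 and a largest adjusted p of 0.0494. Of these genes, 8553 were tested here and 8507 were called in the same direction, and 0 were called in the opposite direction by edgeR. The file does not state the direction of its contrast. Positive values were read as higher in mutants because the signs then matched this fit. The shared direction as a whole follows from that choice and is no separate check of it. Across these genes, which are not independent replicates, the log2 fold changes of the table and of edgeR had r = 0.9999. Another 5001 genes were called here and were not in the table, of which 2612 had an absolute log2 fold change above its minimum. By DESeq2 here, 10738 genes were called above that minimum, of which 8067 were in the table. Absence from the table was thus not particular to edgeR, and its full filter is not stated.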

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

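Reads in place of TPM and the omission of both precursor libraries numbered 1 were chosen after seeing the data; the other settings were planned. The numbers of genes called higher (5630 to 7129) and lower (5937 to 8047) stayed within 1.5 times of the main counts under every scaling, filter, tool and left-out library, and were 2865 and 3564 at an absolute log2 fold change of at least 1, which asks for more by construction. Upper-quartile scaling moved the median log2 fold change of all genes by -0.13. It called 5630 genes higher and 8047 lower, so 41.2% of called genes were higher, against 49% in the main fit. The utp3 log2 fold change ran from -1.71 to -1.51, and 8196 to 8525 genes of the deposited table were called in its direction. An estimated inter-gene correlation widens the variance of the mean of each of these lists, and with 6 libraries that test has few degrees of freedom. Its camera adjusted p-values were 0.28 for exosome, unfolded protein response, exocrine pancreas, intestine, photoreceptor and lens, and inflammation lists, 0.302 for SSU processome and integrated stress response, 0.308 for large subunit assembly and RNA polymerase I, 0.357 for myeloid and lymphoid, 0.399 for neuron and glia, and 0.473 for hepatocyte lists. For the unfolded protein response list the estimate was 0.0297, near the preset 0.01. For that list the size of the correlation alone therefore need not account for the lost call. In the other lists called with the preset, estimates ran from 0.1 (myeloid and lymphoid) to 0.437 (SSU processome), well above it. For those lists the preset understates the correlation that was estimated. With fry, which tests a list without setting it against other genes, the endocrine pancreas list passed as falling (fry adjusted p = 0.00906). The large subunit ribosomal protein list passed without wt13 (adjusted p from 0.00508 to 0.73 with 1 library left out); the cause was not tested. Among named genes, rpl13 without s3 and saa2 with limma voom lost their calls; the cause was not tested. The other 634 named gene values kept direction and side. The 204 list values kept their side of the threshold, but list medians near 0 turned sign: without wt11, small and large subunit ribosomal protein medians were 0.21 and 0.10 and that of skeletal muscle 0.12.

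The planned replicate block was not run on genes or lists. The headings of the gene count columns (s1 to s3, wt11 to wt13) do not state which numbered replicate each holds. A block on the digits of the headings would assume a pairing that no label gives, and was not run. In the precursor table the replicate block gave the same 5'ETS difference of 3.70, with an exact sign-flip p of 0.25, the smallest 3 pairs can give. Deviations of same-numbered libraries correlated at 0.263, -0.781 and 0.537, so the numbers were not taken to pair them; with so few regions this does not show that they are unpaired. By limma the 5'ETS difference of 3.70 passed (adjusted p = 0.0176), a test that pools the spread over regions. Leaving out 1 library gave log2 differences of 3.29 to 4.24 for the 5'ETS, -1.40 to -0.93 for 18S, 2.5 to 3.82 for ITS1, 1.73 to 3.39 for ITS2, and of -0.356 to 0.114 for 28S, whose sign turned without wild type replicate 2 (0.023) or mutant replicate 3 (0.114). Reads in place of TPM gave 3.03 for the 5'ETS, -1.86 for 18S (exact permutation p = 0.3), 2.05 for ITS1, 1.93 for ITS2 and -0.71 for 28S, and without both libraries numbered 1 these were 3.83, -0.74, 3.17, 1.99 and -0.49. The filter on regions with a mean TPM under 1 removed none. Depth limits the spacers, where ITS1 had as few as 3 reads in a library.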

Other observations

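The gene families below and the tests of explanations for the hepatocyte, 5'ETS and ribosome assembly patterns were chosen after the results were seen. The camera p-values of these families were adjusted over the chosen families only and take no account of that choice. They describe the families and are not tests of them. Of 75 mitochondrial ribosomal protein genes, 68 rose and 7 were not called (median log2 0.93, camera adjusted p = 9.38e-13, and adjusted p = 0.324 with an estimated correlation). Of 48 proteasome subunit genes, 43 rose and 1 fell (median log2 1.13, camera adjusted p = 2.1e-10, and adjusted p = 0.324 with an estimated correlation); psme3 rose by log2 2.06 ± 0.10, and the gene that fell was a psme4 copy (ENSDARG00000087911, log2 -1.20). Of 19 cytosolic aminoacyl-tRNA synthetase genes, which charge transfer RNA, 18 rose (median log2 1.90, camera adjusted p = 1.56e-09, and adjusted p = 0.324 with an estimated correlation). The tyrosine enzyme gene yars1 went from 34.0 ± 5.01 to 275.6 ± 15.9 CPM. All 8 genes of the CCT chaperonin rose by edgeR with TMM scaling (median log2 1.05, camera adjusted p = 0.000881, and adjusted p = 0.324 with an estimated correlation), and 7 with upper-quartile scaling. Of 55 translation initiation factor genes, 32 rose and 3 fell (median log2 0.74, camera adjusted p = 4.91e-06, and adjusted p = 0.324 with an estimated correlation); 5 fell with upper-quartile scaling or without wt13. Of 39 respiratory complex I genes, 12 rose (median log2 0.31, camera adjusted p = 0.00802, and adjusted p = 0.672 with an estimated correlation), and 30 rose without wt11. The count of 12 is a share similar to that of all tested genes, of which 6614 of 21708 rose.

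Of 53 cytochrome P450 genes, 31 fell and 6 rose (median log2 -1.48, camera adjusted p = 2.15e-06, and adjusted p = 0.045 with an estimated correlation). The gene cyp3a65 fell from 854.3 ± 81.7 to 17.9 ± 1.14 CPM, and cyp7a1, for the first enzyme of the main bile acid pathway, from 81.9 ± 10.7 to 13.2 ± 4.29 CPM. Of 48 crystallin genes, 41 fell and crygm2c rose (log2 1.54; 2 genes rose without wt12; list median log2 -2.35, camera adjusted p = 2.14e-12, and adjusted p = 0.324 with an estimated correlation). Of 17 nonvisual opsin genes, 12 fell (median log2 -1.40, camera adjusted p = 0.00357, and adjusted p = 0.324 with an estimated correlation). Of 20 keratin genes, 14 fell and 3 rose (median log2 -1.31, camera adjusted p = 0.000881, and adjusted p = 0.324 with an estimated correlation). Among them krt15 fell from 539.4 ± 77.4 to 33.5 ± 0.60 CPM while krt18a.1 rose by log2 2.33 ± 0.18; without wt11, 5 rose. Of 71 genes of laminins and matrix remodelling, 41 rose and 15 fell (median log2 0.60, camera adjusted p = 0.000595, and adjusted p = 0.324 with an estimated correlation). A timp2 copy (ENSDARG00000075261) rose from 12.3 ± 1.15 to 2032 ± 159.7 CPM. Of 28 core glycolysis genes, 10 fell and 7 rose (median log2 -0.12, camera adjusted p = 0.723); 6, 5 and 6 fell without s1, s3 and wt11.

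The real division of the 6 libraries called 13508 genes by edgeR, and the highest count of the other divisions into 3 and 3 was 0, with up to 524 genes at an unadjusted p under 0.05 and 0 by limma voom and DESeq2. Each of the other divisions holds both genotypes on each side, so the genotype difference adds to the spread within sides. Low counts there follow from that and do not measure noise between libraries. With 1 of 10 divisions as large, the divisions are too few for a share under 0.05. Near utp3, within 10 Mb, 182 of 268 tested genes were called (81 higher, 101 lower), a share of 67.9% against 62.3% of 20743 genes on other chromosomes. The ratio of the shares was 1.09 (odds ratio 1.28, 95% interval 0.985 to 1.68, Fisher exact p = 0.0656). An effect of alleles linked to utp3 on nearby genes cannot be told apart from no such effect, because the interval holds both.

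In the hepatocyte list 21 of 33 genes fell and 8 rose (median log2 -1.08, camera adjusted p = 0.00089, and adjusted p = 0.473 with an estimated correlation). Fewer hepatocytes with unchanged expression per cell would lower all of their transcripts, which leaves the fibrinogen genes fga, fgb and fgg unaccounted for: these members, already seen to rise, had a median log2 fold change of 2.00. Fibrinogen is made in the acute phase, and 24 of 26 inflammation and acute phase genes rose (median log2 3.84), so fewer hepatocytes together with induction of such genes may account for the genes that fell, which was not tested. Scaling between libraries would need a shift of the size of the list median, and the largest shift of the median of all genes over other scalings and tools was 0.132. These scalings are all set from the counts themselves, so a shift common to most genes would not show in them.

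The 5'ETS share of the precursor was higher in the mutants. Unequal carry-over of mature rRNA would change the share and leave the reads of the 5'ETS overlapping, but the lowest mutant library had 1.8 times the 5'ETS reads of the highest wild type library. That premise is limited, since wild type replicate 1 had both the most 5'ETS reads of its group (455) and the most precursor reads (653430). Deeper sequencing of the mutants could raise reads only as far as depth differed. The largest gene count total was 1.12 times the smallest, but such totals count reads assigned to genes and do not measure depth itself. Slower removal of the 5'ETS and faster transcription of the precursor stay open, and neither was tested. The libraries are of polyA RNA per the labels, so 5'ETS reads also depend on what passed that selection, which was not measured.

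Ribosome assembly genes were higher while ribosomal protein genes were mostly not called, the latter with counts that depended on wt11 and wt13. A larger share of proliferating cells, with expression per cell unchanged, would raise the proliferation list alike. The median log2 fold change of that list was 0.10 (bootstrap 95% interval over genes -0.12 to 0.28), below 0.6, the bound set from the SSU processome median. The interval draws genes as if independent, though their estimated correlation was 0.218, and carries no spread between libraries. The median was 0.239 without wt11 and -0.032 with upper-quartile scaling. Expression per cell was not measured. At least 50 of the SSU processome members were higher over the 4 other scalings and tools, of which limma voom used the same TMM factors. Each of these sets the level of a library from its own counts, so none can show a shift common to most genes. The choice among these scalings did not account for the calls, and such a common shift was not tested. A response of assembly genes to the mutation is a candidate explanation that these data did not test.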
